A study of Chlorocebus sabaeus with 6 samples.

How the data were processed

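Messenger RNA was sequenced from 6 libraries of COS-1 cells, a line derived from African green monkey (Chlorocebus sabaeus) kidney fibroblasts transformed with simian virus 40 sequences. Per the labels, 3 libraries came from control cells that received no treatment and 3 from lentivirus-treated cells. Per the labels' protocols, all 6 cultures were starved of serum for 14 h and then given epidermal growth factor (EGF) at 2 ng/ml for 90 min, so the comparison is between the groups in the EGF-treated state and holds no unstimulated sample. Poly-A RNA was isolated and made into cDNA libraries, per the labels' protocols. Nothing in the labels says whether the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

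The authors deposited 1 table of FPKM values (fragments per kilobase of feature, scaled to library size), with 1 column per library and 1 row for each of 51520 features. Per the submitters' processing notes, CASAVA, TopHat2 2.0.10, Bowtie2 2.1.0.0, Cufflinks 2.1.1 and Cuffdiff were used; the role and order of these tools, any scaling between libraries and the genome build are not given in the sources used here. Positions below are those of the deposited table. The columns summed to between 2094230 and 2206930 FPKM per library. Features were named by accessions: 19602 began with ENSP, 31829 with JK and 89 with other letters. The deposited table pairs no accession with a gene symbol, and 0 of the 51520 IDs matched the RefSeq gene table of assembly mChlSab1.0.hap1. SHOC2, the protein named in the series title, and the 28 gene lists fixed before the data were examined were therefore not analysed here, and no gene was named from its ID or position.

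FPKM keeps no read counts. Only 2 of the 14130 features that overlap no other had all 6 values above 0 and below 0.3 FPKM, too few to read the size of 1 read from the low values, so the depth of each library is unknown and no counting interval is given. Between 1170 and 1231 features per library stood at exactly 0, and between 13094 and 13344 were under 0.0001 FPKM.

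Features with a mean of at least 1 FPKM over the 6 libraries were tested (28434 of 51520) on log2(FPKM + 1) with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3, as fixed before the data were examined. All 6 libraries entered 1 model with the group as its only term. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all tested rows, and a row was called at an adjusted p under 0.05. A fold change on the log2(FPKM + 1) scale understates the change of low features. An exact permutation test of 3 against 3 libraries cannot go below p = 0.10.

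Several steps were chosen after the values had been seen. Features whose positions overlapped were joined into 20566 loci, without regard to strand, which the table does not give, and the FPKM values of a locus were summed; 16073 loci had a mean of at least 1 FPKM and were tested in the same way. A locus can hold parts of more than 1 gene. Each chromosome with at least 50 tested loci was tested as a set with camera from limma, with its preset correlation of 0.01 and, as an alternative, with an estimated correlation. The median log2 change was taken over windows of 20 consecutive loci, moved in steps of 5. A window was called when its absolute median exceeded 0.267, the 95th percentile of the largest absolute window median in 500 shuffles of the loci over the genome. The shuffles treat loci as exchangeable and take no account of the spread between libraries. Where neighbouring loci move together for any reason, such as being parts of 1 gene, the threshold does not hold the error rate its percentile implies. Called windows of 1 direction that overlapped each other, directly or through windows between them, were joined into regions, so region ends are known only to within about a window. The value of a chromosome or region in a library is the median over its loci of log2(FPKM + 1) minus the mean of that locus over the 6 libraries.

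The rule for naming genes, fixed before the data were examined, required a gene symbol and so named none. In its place, the rule's other criteria (a call, at least 5 FPKM in the higher group, groups that do not overlap) were kept, at least 1 FPKM was required in every library, and the largest changes each way were taken, limited to features that overlap no other when single features were named. That limit was added after a first version had taken a feature from a crowded locus and its values had been seen.

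The feature and locus tests were tested on simulated data drawn from the means and spreads of the real rows, with 200 rows changed. Among 28434 simulated features, 32.8% of those changed by 0.5 log2 were recovered, 65.7% of those changed by 1 and 78.8% of those changed by 2. The 13 false calls stood beside 22, 44 and 52 recovered features. Among 16073 simulated loci, 56.7%, 83.6% and 97.0% were recovered at the same sizes, with 9 false calls. Benjamini-Hochberg calls depend on the share of changed rows. In the real data 6.48% of features and 19.5% of loci were called, so these recovery rates need not carry over. Of 4 chromosomes with a simulated stretch of 60 loci shifted by 0.3 log2, 4 had a region called, with 0 regions on other chromosomes. False regions on the same chromosomes were not counted. Each simulated locus was drawn independently of its neighbours, so the 0 does not cover libraries in which neighbouring loci move together.

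Whether the replicate numbers in the labels pair the libraries is not known. The correlation of deviations from the group means between libraries of the same number was 0.13, -0.028 and 0.0028 over features. Over loci it was 0.077, 0.027 and -0.019. Libraries of different numbers were not compared in this way. Alternatives planned in advance were other pseudocounts, filters and scalings, limma without the trend or with robust fitting, a replicate block, and leaving out each library in turn; the planned sum of rows with 1 gene symbol and the planned tests of gene lists were not run because no row had a symbol.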

Results

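The data collected were FPKM values of 51520 features in 6 COS-1 libraries, 3 from control cells and 3 from lentivirus-treated cells, all sampled after serum starvation and 90 min of EGF. The series title places the experiment in a study of SHOC2, a scaffold protein of the RAS to ERK1/2 signalling cascade, but the labels do not say what the lentivirus carried. Between 27605 and 27874 features per library reached 1 FPKM, and the 10 most abundant features held 12.3% to 13.2% of each library's FPKM. The number of reads per library is unknown.

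Libraries of 1 group resembled each other closely once overlapping features were summed. Over the 16073 tested loci, Pearson's r of log2(FPKM + 1) across loci, which are not independent replicates, was 0.990 to 0.992 within a group and 0.986 to 0.988 between groups. Over the 28434 tested features it was 0.941 to 0.953 within a group and 0.935 to 0.949 between groups. The median within-group SD of a feature rose with crowding, from 0.10 log2 for features that overlapped no other to 0.25 for features in loci of over 20 features.

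The first comparison asked which features differed between lentivirus-treated and control cells. By limma with Benjamini-Hochberg adjustment, 821 of 28434 features rose and 1021 fell. Most changes were small: the median absolute log2 change of called features was 0.42, and 41 features rose and 78 fell by at least 1 log2. On the TPM scale 869 features rose and 870 fell, 32 and 49 of them by at least 1 log2. Under median ratio scaling 872 rose and 1013 fell, and under quantile normalization 869 rose and 1044 fell. Features named ENSP were called more often than those named JK, with 1270 of 13509 (543 up, 727 down) against 572 of 14915 (278 up, 294 down); the 10 tested features with other accessions gave 0 calls, with 4 at an unadjusted p under 0.05. The groups did not overlap in any of the 1842 called features, and in 31.6% of all tested features, where chance gives 10% for a single feature. The features come from the same 6 libraries and are not independent.

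Among features that overlap no other, 2 that rose and 2 that fell were singled out after their values were seen, as the largest changes that met the criteria. ENSP00000368104 (chromosome 2, 31350277 to 31359222) rose 3.81-fold, from 5.96 ± 0.735 to 22.7 ± 1.11 FPKM (SD, n = 3 per group), a log2 change of 1.77 with SE 0.095 and a limma adjusted p of 0.00529. JK112617.1 (chromosome X, 8599092 to 8599259) rose 3.51-fold, from 2.57 ± 0.538 to 9.03 ± 2.30 FPKM, with a limma adjusted p of 0.0224. ENSP00000401764 (chromosome X, 62126462 to 62127674) fell 5.34-fold, from 47.0 ± 4.53 to 8.79 ± 0.219 FPKM, a log2 change of -2.29 with SE 0.078 and a limma adjusted p of 0.00252. ENSP00000249750 (chromosome 26, 25439512 to 25555384) fell 3.95-fold, from 46.8 ± 1.69 to 11.8 ± 0.370 FPKM, a log2 change of -1.90 with SE 0.050 and a limma adjusted p of 0.00182. The exact permutation p of each was 0.10, the smallest that 3 against 3 libraries allow. In the test over all features, JK112617.1 lost its call without any 1 of the 6 libraries, with log2 changes of 1.30 to 1.60. Tested among the loci with the same values, it had a limma adjusted p of 0.00540 and kept its call without any 1 library.

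**Figure D1:**
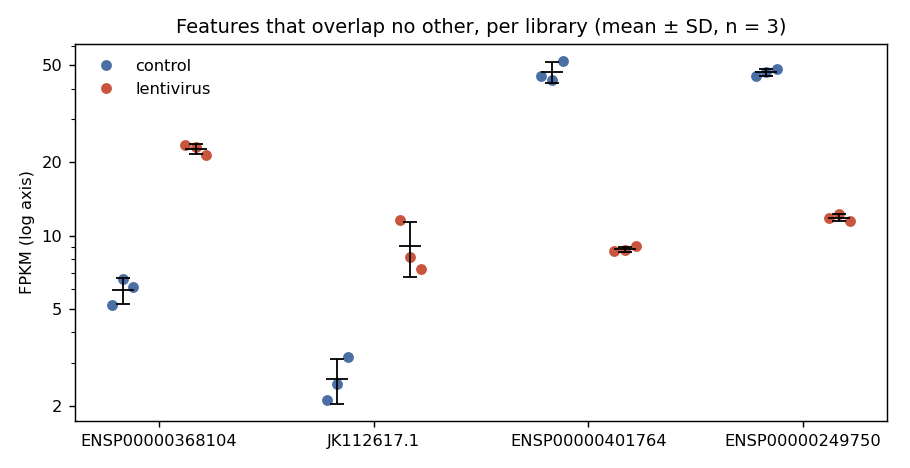
FPKM (log axis) of the 4 features singled out, with 1 point per library, control in blue and lentivirus-treated in red, and black bars for the mean ± SD of 3 libraries. ENSP00000368104 and JK112617.1 sit higher in all 3 lentivirus libraries, and ENSP00000401764 and ENSP00000249750 sit lower, from 47.0 to 8.79 and from 46.8 to 11.8 FPKM.

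The number of called features rested on having all 6 libraries. Without control replicates 1, 2 and 3 it was 67, 108 and 63, and without lentivirus replicates 1, 2 and 3 it was 48, 79 and 90. The 119 calls of at least 1 log2 became 37 to 54 without 1 library, and 181 and 53 at pseudocounts of 0.1 and 5.

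Summing overlapping features gave more calls with smaller changes. By limma with Benjamini-Hochberg adjustment, 1427 of 16073 loci rose and 1707 fell, with a median absolute log2 change of 0.34; 21 loci rose and 50 fell by at least 1 log2. On the TPM scale 1507 loci rose and 1469 fell. Under median ratio scaling 1518 rose and 1608 fell, and under quantile normalization 1505 rose and 1600 fell. Without control replicates 1, 2 and 3 the calls numbered 1799, 2232 and 1557, and without lentivirus replicates 1, 2 and 3 they numbered 1879, 1443 and 1607. Calls of at least 1 log2 numbered 68 to 83 in these fits, against 71 with all libraries, but 142 and 26 at pseudocounts of 0.1 and 5 and 45 on the TPM scale.

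The loci with the largest increases lay on several chromosomes. On chromosome 1, the locus from 119827221 to 119944678 rose 3.92-fold, from 7.19 ± 0.829 to 28.2 ± 0.981 FPKM (SD, n = 3), and its 3 tested features were all called up. A second locus on the same chromosome, from 119588964 to 119589575, rose 3.17-fold, from 4.70 ± 0.885 to 14.9 ± 1.22 FPKM, with 2 of 3 tested features called up. On chromosome X, the locus from 76157345 to 76316368 rose 3.37-fold, from 2.03 ± 0.0857 to 6.84 ± 0.335 FPKM. On chromosome 27, the locus from 1363807 to 1378129 rose 2.62-fold, from 10.8 ± 0.419 to 28.3 ± 1.88 FPKM. On chromosome 20, the 13-feature locus from 4891935 to 4928701 rose 3.12-fold, from 2.90 ± 0.401 to 9.03 ± 1.01 FPKM, with 0 of 2 tested features called. The limma adjusted p of these 5 loci ran from 5.76e-04 to 0.00234. A short locus on chromosome 29, from 23717834 to 23717928, had the largest fitted rise, 2.89 log2, but its control values were 21.9 ± 21.5 FPKM and its call was lost in 4 of the 6 fits that left out a library. Short loci on chromosomes 3 (78715916 to 78716074, 4.66-fold) and 11 (10009831 to 10009956, 3.10-fold) lost their call in 5 and 2 of these fits.

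Falling loci included 2 sets of close neighbours. On chromosome 16, the loci from 70941895 to 70942100 and from 70942207 to 70947710 fell 2.74-fold and 3.06-fold, the latter from 126.9 ± 9.83 to 41.5 ± 1.59 FPKM. On chromosome 8, the loci from 127668013 to 127668198 and from 127669718 to 127714679 fell 2.77-fold and 2.74-fold, the latter from 81.5 ± 5.94 to 29.7 ± 1.97 FPKM. On chromosome 1, the locus from 49841481 to 49843912 fell 3.06-fold, from 35.3 ± 4.56 to 11.5 ± 0.528 FPKM. On chromosome 7, the locus from 113043385 to 113531119 fell 3.71-fold, from means of 6.33 to 1.71 FPKM (log2 change -1.44, SE 0.11). On chromosome 9, the locus from 44908408 to 44912400 fell 2.86-fold, from 23.4 ± 3.58 to 8.18 ± 1.80 FPKM. All 7 kept their call without any 1 library, and their limma adjusted p ran from 4.52e-04 to 0.0048.

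The second comparison asked whether the changes were spread evenly over the genome. They were not: the loci of some chromosomes were shifted as a set. Chromosomes 26, 15, 14, 8 and 6 were lower as sets and chromosomes 20, 24, 17, 23, 10, 27, 21 and 13 were higher, by camera with Benjamini-Hochberg adjustment over 30 chromosomes. With an estimated correlation, the calls of chromosomes 6, 21 and 13 were lost (camera adjusted p = 0.52, 0.10 and 0.11) and chromosome 9 was gained, higher in the lentivirus-treated libraries (camera adjusted p = 0.042). The library medians of chromosome 26 were 0.096 ± 0.0046 log2 in control and -0.088 ± 0.014 in lentivirus-treated libraries (SD, n = 3), and 20.6% of its 422 loci had a positive change (camera adjusted p = 3.84e-10). Those of chromosome 15 were 0.086 ± 0.010 and -0.082 ± 0.0041, with 24.9% of 378 loci positive (camera adjusted p = 2.82e-08). Those of chromosome 20, the highest, were -0.052 ± 0.011 and 0.052 ± 0.0093, with 70.3% of 1149 loci positive (camera adjusted p = 3.86e-07). Chromosome 24 followed with 69.4% of 474 loci positive (camera adjusted p = 1.11e-05). These values rest on the preset correlation. With the estimated correlation the camera adjusted p was 0.0025 for chromosomes 26, 15 and 24 and 0.0059 for chromosome 20.

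The groups did not overlap in 23 of 30 chromosomes, where chance gives 10% for a single chromosome. The 30 chromosomes come from the same 6 libraries and are not independent, so the count cannot be set against that rate as a test. The groups did overlap on chromosome 6, whose control libraries had medians of 0.061, -0.022 and 0.061 log2.

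**Figure D2:**
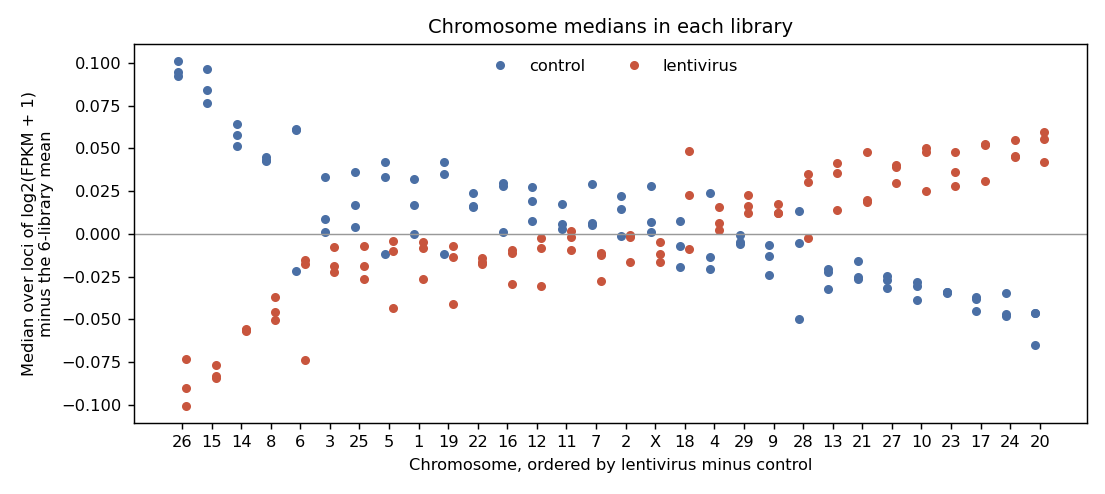
Median over loci of log2(FPKM + 1) minus the 6-library mean, for each of 30 chromosomes on the horizontal axis, with 1 point per library (control blue, lentivirus-treated red). Chromosome 26 at the left has control libraries near 0.096 and lentivirus libraries near -0.088, and chromosome 20 at the right has the reverse order, near -0.052 and 0.052.

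Within chromosomes the shift varied along the sequence. Of 3135 windows of 20 loci, 24 were higher and 45 lower past the shuffle threshold of 0.267 log2, and they joined into 7 higher and 10 lower regions that cover 116.5 Mb and 3.84% of tested loci. The balance of directions depended on the scale: on the TPM scale there were 16 higher and 9 lower regions. On chromosome 18 a region from 35062171 to 56122984 was 1.23-fold higher: its 50 loci had a median change of 0.30 log2, with library medians of -0.16 ± 0.020 in control and 0.16 ± 0.0071 in lentivirus-treated cells (SD, n = 3). The chromosome as a whole was not called (camera adjusted p = 0.10). On chromosome 21, 3 higher regions lay beyond 101477255, from there to 108043520 (median 0.27 log2), from 109490333 to 118517933 (0.30) and from 123745174 to 126869489 (0.28).

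On chromosome 26, 4 lower regions lay between 18292555 and 48566402, with median changes of -0.28 to -0.32 log2. In the first of them, from 18292555 to 24919006, 94% of 50 loci were lower. On chromosome 15, the regions from 3807184 to 12402905 and from 17029963 to 39605219 had median changes of -0.34 and -0.29 log2, and the region from 84518893 to 91134212 had one of -0.28. The other regions lay on chromosomes 10 (59945485 to 64012906, 0.25 log2), 20 (97003568 to 99863501, 0.32), 24 (1035946 to 1648084, 0.27), 25 (81442890 to 85764067, -0.27), 6 (41656333 to 42145217, -0.28) and 8 (85137530 to 89739744, -0.30). In all 17 regions the 3 control and the 3 lentivirus libraries did not overlap; the regions were drawn on these same values, so that count is not independent evidence.

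**Figure D3:**
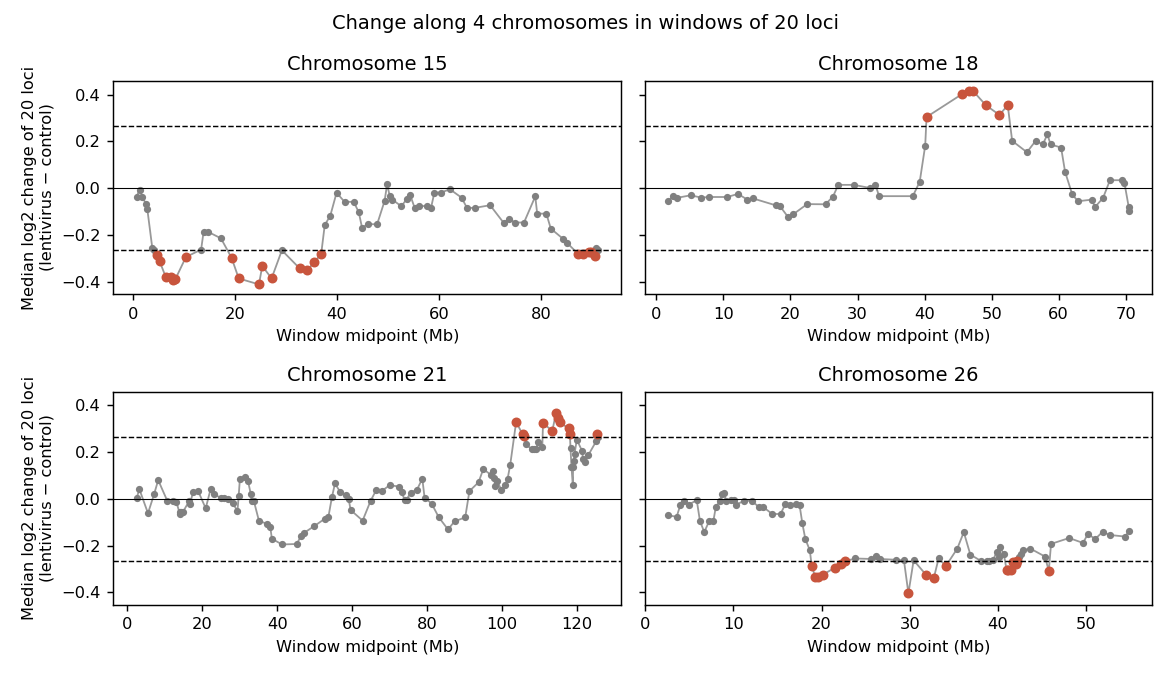
Median log2 change (lentivirus minus control) of windows of 20 loci against the window midpoint in Mb on chromosomes 15, 18, 21 and 26. Dashed lines mark the shuffle threshold of 0.267 either way, red points lie past it and grey points within it; on chromosome 26 the windows lie nearer 0 before the first lower region, which starts at 18292555, and all lie below 0 from there on.

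**Figure D4:**
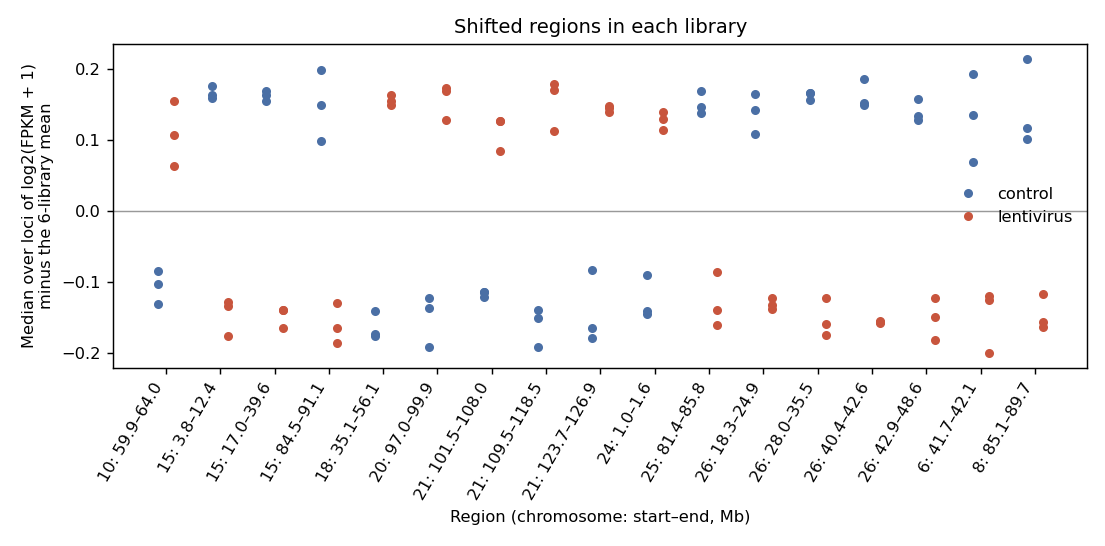
Median over loci of log2(FPKM + 1) minus the 6-library mean in each of the 17 regions, with 1 point per library (control blue, lentivirus-treated red). In each region the libraries of the 2 groups lie on opposite sides of 0, such as 0.16 ± 0.0071 against -0.16 ± 0.020 on chromosome 18.

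Most called loci lay outside these regions. The lower regions held 192 of the 1707 called lower loci (11.2%) and 2.41% of all tested loci. The higher regions held 115 of the 1427 called higher loci (8.06%) and 1.43% of all tested loci. These excesses follow from drawing the regions on the same changes. Of the 71 called loci with a change of at least 1 log2, 67 lay outside the regions. When the median change of its neighbours was subtracted from each locus in each library, an alternative chosen after the data were seen, limma called 1888 loci in place of 3134, and 61 in place of 71 with a change of at least 1 log2.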

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

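All alternatives for loci, chromosomes and regions, and those that sum features or keep only lone ones, were chosen after the data were seen; the others were planned. The count of 1842 features fell to 1220 with no filter, was 3134 when overlapping features were summed to loci, and ran from 48 to 108 when 1 library was left out. With the replicate number as a block limma called 0 features, also 0 at 1 log2 or more, and 1774 in place of 3134 loci. In that fit 6084 features had an unadjusted limma p under 0.05, against 6890 without the block. The block costs residual degrees of freedom, and whether the numbers pair the libraries is not known. Counts at 1 log2 or more depended on the pseudocount by construction: 119 features became 181 at 0.1 and 53 at 5, and 71 loci became 142 and 26, and 45 on the TPM scale. Those 119 features became 71 when summed to loci, 50 among lone features, and 37 to 54 without 1 library. Locus calls ran from 1443 to 2232 without 1 library and were 1888 after subtracting the median of the neighbours. The 17 regions (7 higher, 10 lower) became 28 (14 and 14) at a pseudocount of 5 and 11 (3 and 8) with windows of 10 loci; on the TPM scale there were 25 (16 and 9). Over all calls, the excess of falling features and loci was absent on the TPM scale (869 features up and 870 down, 1507 loci up and 1469 down). TPM values were lower than FPKM values here, so the same pseudocount weighed more on the TPM scale. Under median ratio scaling the excess remained (872 features up and 1013 down, 1518 loci up and 1608 down). Under quantile normalization it remained too (869 features up and 1044 down, 1505 loci up and 1600 down). Among calls of 1 log2 or more the excess remained on the TPM scale (32 features up and 49 down, 16 loci up and 29 down). The cause was not tested. The signed median of the regions, 0.286 log2, was 0.321 and 0.210 at pseudocounts of 0.1 and 5, 0.317 at a filter of 5 FPKM and 0.254 on the TPM scale. Under median ratio, quantile and TPM scaling, 13 of 13 called chromosomes, 17 of 17 regions and 20 of 20 top loci kept their direction, and the 13 chromosomes their call. The median of all loci moved from -0.0056 to at most 0.012 log2. The smallest signed median of a region was 0.247 log2 without scaling. It was 0.256, 0.246 and 0.211 log2 under median ratio, quantile and TPM scaling. The directions of the regions and top loci could therefore hardly have changed. Among the 4 features singled out, no direction reversed. The block ended each call (limma adjusted p = 0.121 to 0.131), and JK112617.1 also lost its call with no filter (limma adjusted p = 0.0517) and without any 1 library (limma adjusted p = 0.0643 to 0.0868). Those losses were in the test over all features. Tested as a locus, JK112617.1 kept its call without any 1 library. The planned SHOC2, gene list and summed-symbol alternatives were not run, as no row had a symbol. Depth is unknown, so the share of the spread owed to counting was not estimated.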

Other observations

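The patterns below were found in the data. The tests of left-out loci for a few strong loci, for single features and for a trend, and the count of splits for features, were chosen after the result was seen; the tests by expression level, of shared loci and of the other splits were written down before their own results. The single-feature and trend tests were first run on the loci that defined the regions (0.281 and 0.284 log2) and then moved to left-out loci.

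The most abundant locus, on chromosome 17 from 1626896 to 1630445, joined 545 features and held 7.99% of all FPKM. Its summed value was 162012 ± 3860 FPKM in control and 182160 ± 5795 in lentivirus-treated libraries (SD, n = 3), a log2 change of 0.17 with a limma adjusted p of 0.0701. A single short feature on chromosome 14, from 29860074 to 29860137, held 1.86% of all FPKM and fell from 47417 ± 3851 to 32574 ± 1188 FPKM (log2 change -0.54, limma adjusted p = 0.00585). On chromosome 1, the locus from 46452554 to 46542400 fell by 0.31 log2 (limma adjusted p = 0.0234) and the locus from 11327091 to 11339372, with 124 features, fell by 0.18 log2 (limma adjusted p = 0.0303).

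Neighbouring loci moved together over long stretches. To test this away from the loci that defined it, regions were drawn again from every second locus, which gave 10 regions, and measured on the 337 loci left out. The left-out loci alternate with those used for drawing, come from the same 6 libraries, and can be parts of the same gene as a neighbour. They are therefore not an independent sample. Of the 337 left-out loci, 85.5% moved the way of their region, against 51.1% of all loci with a negative change. Since a window was called on the median of its 20 loci, a few strongly changed loci could not have formed a region. The 85.5% therefore does not test that explanation, and shows only that the shift extended to the left-out loci. Reads moved between overlapping features are argued against, since the 215 left-out loci of a single feature had a signed median of 0.235 log2. A smooth trend with locus density and expression level is also argued against, since 0.226 log2 remained after its removal. The left-out median was between -0.0117 and 0.00938 log2 in the 6 pairs of libraries within a group and between 0.231 and 0.255 in the 9 pairs between groups. A candidate explanation is a different copy number of these chromosome parts in the lentivirus-treated cells, which predicts a shift at every expression level. The signed medians were 0.140, 0.280 and 0.276 log2 in the low, middle and high expression classes, all above the 0.1 asked for in advance. The regions were drawn for their shift, and all 337 left-out loci had a median of 0.235 log2, so this bound was easy to meet. Regional regulation or a bias shared by a group could meet it as well, so the result does not single out copy number. DNA was not measured. GC content was not tested, and the genome build of the deposited positions is not given. Neither a bias shared by the libraries of 1 group nor regional regulation by the treatment is excluded.

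Large changes of single features in crowded loci often did not carry over to the locus. Of 79 called features with a change of at least 1 log2 that shared a locus, 54.4% lay in a locus whose sum was called the same way, and the median absolute change was 1.47 log2 for the features and 0.35 for their locus sums. An example picked for its opposed calls is the locus on chromosome 20 from 12291728 to 12294096, where 1 feature had a log2 change of 3.998 and another of -3.08 (limma adjusted p = 0.0450 and 0.0157), while their locus sum had a log2 change of 0.21 (limma adjusted p = 0.115). Reads assigned differently among overlapping features may account for part of these calls. The 54.4% lies between the bounds set beforehand, so such reassignment and real isoform changes cannot be told apart for the set as a whole. FPKM is scaled to feature length, so a locus sum can itself change when reads move between features of unlike length. Over all sizes of change, 79.0% of the 970 called features in shared loci had a locus sum called the same way.

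The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05, and in each count below 1 split, the real one, gave the largest result. Every other split put libraries of both groups on each side, so its contrast kept part of the group difference and its spread took up the rest. The other splits therefore do not show what libraries without a group difference would give. The real split gave 1842 called features, against 18 in the highest other split, and 3134 called loci against 1. It gave 69 windows past the threshold against 19, and 13 chromosomes past camera against 7. The correlation across loci between a locus and the median of its 20 nearest neighbours was 0.284 in the real split and 0.152 in the highest other split. For differences of 2 single libraries it was between -5.40e-04 and 0.0817 within a group and between 0.195 and 0.227 between groups.

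On 11 of 30 chromosomes, control replicate 2 and lentivirus replicate 3 both had the lowest median of their group, such as -0.022 and -0.074 log2 on chromosome 6. On 1 chromosome both had the highest. This pair was picked after the values had been seen, from the 9 pairs of a control and a lentivirus library.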
